A study of Mus musculus with 12 samples.

How the data were processed

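Gene counts were analysed from 12 RNA-seq libraries of mouse embryonic fibroblasts, 3 in each of 4 groups that combine a control or an IMP2 siRNA with no stimulus or IL-17. Per the labels' protocols, RNA was taken with a column kit and libraries followed a standard Illumina protocol. The deposited counts are whole-number counts of reads per gene, not normalised. Reads were paired and trimmed, per the file headers, and the genome build was mm10, per the submitters' processing notes. The aligner, the counter, their versions and the use of strand are not given in the sources used here. Counts of overlapping, antisense and paralogous genes, Igf2bp1, Igf2bp2 and Igf2bp3 included, are therefore uncertain where reads could be shared. The deposited log2 fold changes are the authors' own, for 4 comparisons of the groups, and the deposited p-values are the authors' values adjusted for the false discovery rate, per the file headers, with the test and model not given in the sources used here. The 12 count columns of the series table equalled the 12 per-library files, 0 per-sample count columns were unused, and 0 of 48709 genes had no name. Of the gene identifiers 48349 (99.26%) matched the GENCODE mouse annotation used for transcript length, GC content and 3' UTR sequence, and 42749 (88.42%) had the same coordinates there. Coordinates are those of the deposited files.

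Groups came from the labels, and the title set (NA or RB160) from the start of each title. Replicate numbers follow accession order and pair no libraries. Total counts per library were 37481186, 33841054 and 37772710 in siControl, 38540020, 34510682 and 44433699 in siControl_IL17, 37543221, 37071000 and 39746828 in siIMP2, and 35466041, 34462068 and 41752198 in siIMP2_IL17, so 1 CPM, scaled by the TMM factors, stands for 31.9 to 50.9 reads. Bounds from counts of 0 cover counting error only.

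Counts were fitted with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with a minimum count of 10 and a minimum total of 15, and a quasi-likelihood fit over all 12 libraries with the 4 groups and the title set as terms. The 13702 genes that passed the filter were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were IL-17 against no stimulus with each siRNA, the IMP2 siRNA against the control siRNA without and with IL-17, the difference of the IL-17 responses, and the averages of both effects. Log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and lists with at least 3 measured members were tested. No camera call of any list in any comparison passed with an estimated correlation. A fold change against a group with counts of 0 was bounded with a floor of 3 counts over the group. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures, and mgcv 1.9.3 for the trends with GC content and length.

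The tests, alternatives, 32 gene lists and rule for named genes were fixed before the data were examined. The lists hold IL-17 target genes, C/EBP family and target genes, NF-kB, chemokine, IL-17 receptor signalling, RNA-binding regulator, m6A, IMP-bound, extracellular matrix, metalloproteinase, contractile, interferon, oxidative phosphorylation, glycolysis, cholesterol, cell cycle, p53, unfolded protein response, immediate early, ribosomal, sex-linked and mitochondrially encoded genes, and markers of fibroblasts, macrophages, endothelium, epithelium, erythroid cells, neural cells, skeletal muscle, adipocytes, and chondrocytes or osteoblasts. Of the 20 C/EBP target genes 9 are also in the IL-17 target list, as are 7 of 28 chemokines and 3 of 20 NF-kB genes. Named genes were a panel of 16, the 8 genes of smallest p per direction among called genes with the same sign in both sets, a mean log2 CPM of at least 1 and an established symbol, and up to 4 measured members of smallest p per list. Called members named only because few members of a list moved that way, which include Cxcl16, Ptgs2, Il34, Rela, Sesn1, Col1a1, Calr, Pdia3, Egr3, Junb, Ythdf1, Oasl2 and Pdk1, were chosen after their values were seen. Some genes that the rule takes are not reported here.

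Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter beyond 1 count, at least 1 CPM in 3 libraries, no title-set term, the NA libraries alone, only the groups compared, a robust fit, a log2 fold change of at least 1, each library left out, and for lists an estimated correlation, a prior count of 0.5 and fry. Uniquely mapped reads and offsets for GC content and transcript length were added after seeing the data. The method was tested on simulated counts with 200 changed genes. At 1.5-fold and 2-fold edgeR recovered 73% and 77% for the siRNA comparison in unstimulated cells, 67% and 85% for IL-17 with the control siRNA, and 48% and 70.5% for the difference of the responses. In a simulation where the IL-17 response was halved with the IMP2 siRNA, limma's fry gave a p of 1.59e-10 for a common direction, against 0.255 without a difference. The simulation gave its responding genes a 2-fold IL-17 effect, alike in both title sets and with no siRNA effect. In the data 36 of the 373 genes called for the average IL-17 effect reached 2-fold, so the simulation can overstate the power there.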

Results

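RNA from mouse embryonic fibroblasts was sequenced after transfection with a control siRNA (siControl) or with an siRNA against IMP2 (siIMP2). IMP2, encoded by Igf2bp2, is an RNA-binding protein that reads N6-methyladenosine in mRNA. The fibroblasts came from mid-gestation C57BL/6 embryos, and 24 hours after transfection they were left unstimulated or received 200 ng/mL of interleukin-17 (IL-17) for 8 hours. IL-17 is a cytokine that induces chemokines and acute-phase genes in stromal cells. Each of the 4 groups (siControl, siControl_IL17, siIMP2 and siIMP2_IL17) held 3 libraries, and total gene counts ranged from 33841054 to 44433699 per library. The library titles form a set that begins with NA, with replicates 1 and 2 of every group, and a set that begins with RB160, with replicate 3 of every group. Because every group holds both sets, the set was a term in all models, and values within each set stand beside the pooled ones as NA and RB160 values. A principal component analysis of log2 CPM (library-size-scaled counts) put 62.1% of the variance on a first component that separated the sets and 17.3% on a second that separated the siRNAs within each set. Between the sets 9521 of 13702 genes differed, 4778 higher and 4743 lower in RB160, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nothing in the labels states that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No replicate pair of a group matched within sampling noise, with chi-square per degree of freedom from 9.11 to 233, and every library counted as 1 sample. Below, edgeR adjusted p means that quasi-likelihood test with Benjamini-Hochberg adjustment over all 13702 genes, fold changes are log2 values with the standard error (SE), n = 3 per group, and a gene rose or fell when its adjusted p was below 0.05.

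**Figure D1:**
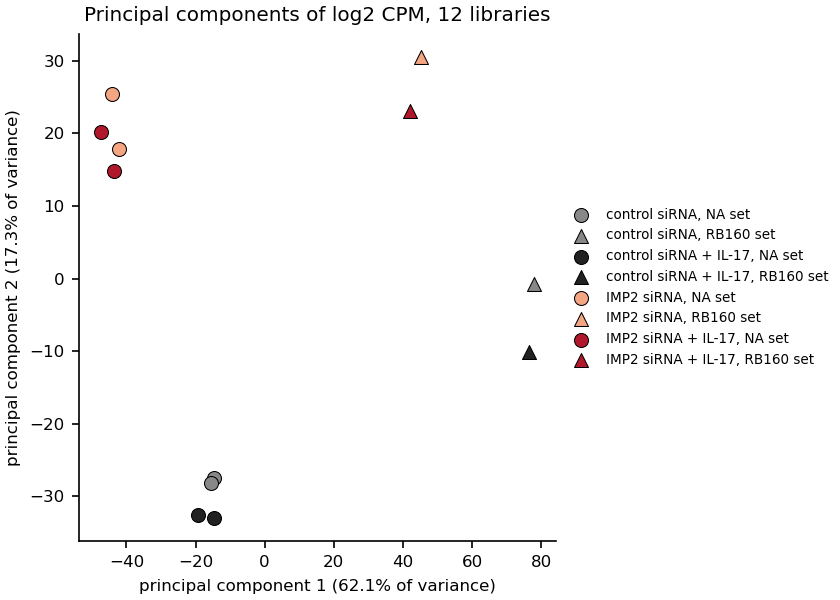
Principal component scores of the 12 libraries from log2 CPM, with the share of variance on each axis, colour for the group and marker for the title set. The 4 RB160 libraries lie at scores from 42.01 to 77.92 on component 1, and the 8 NA libraries lie from -47.33 to -14.62.

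The siRNA target was measured first. Igf2bp2 (ENSMUSG00000033581, mm10 chromosome 16, 22059009 to 22163299, minus strand) stood at 149 ± 17.1 CPM (SD, n = 3) in siControl and 21.9 ± 3.01 CPM in siIMP2, and at 154 ± 13.5 CPM in siControl_IL17 and 23.6 ± 4.90 CPM in siIMP2_IL17. The IMP2 siRNA left 14.7% of the siControl level in unstimulated cells and 15.4% after IL-17. The log2 fold change was -2.77 ± 0.15 unstimulated (edgeR adjusted p = 1.58e-07, NA -2.94, RB160 -2.44) and -2.70 ± 0.15 after IL-17 (edgeR adjusted p = 2.04e-07, NA -2.93, RB160 -2.31). An exact two-sided permutation test of log2 CPM within title sets over the 6 siIMP2 and 6 siControl libraries gave p = 0.00476, the smallest value that its 420 permutations can give. Of its paralogs, Igf2bp1 did not pass (0.08 ± 0.06 unstimulated, edgeR adjusted p = 0.332, and 0.04 ± 0.06 after IL-17, 0.628). Igf2bp3 fell by 0.40 ± 0.08 unstimulated (edgeR adjusted p = 0.002) and by 0.40 ± 0.08 after IL-17 (0.00166). IL-17 moved none of the 3 past the threshold with either siRNA.

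**Figure D2:**
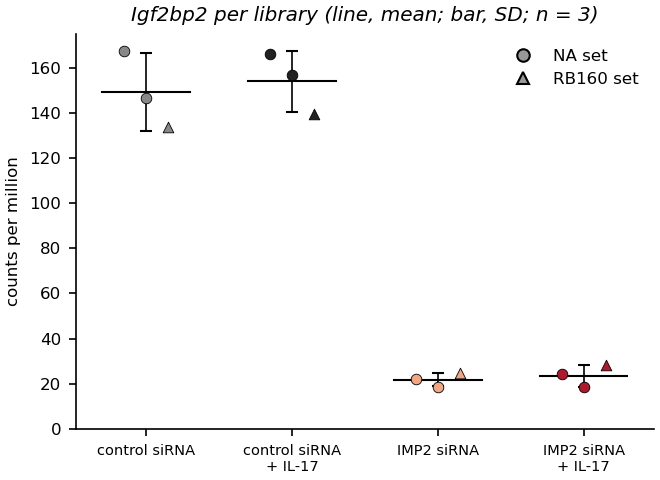
Igf2bp2 level in CPM per library in the 4 groups, with each point 1 library, marker for the title set, and the mean and SD of each group drawn. The siControl groups average 149 and 154 CPM, and the siIMP2 groups average 21.9 and 23.6 CPM.

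The first comparison asked which genes respond to IL-17 in cells with the control siRNA. Of 27 measured genes listed as IL-17 targets 7 rose and 0 fell, with adjusted p = 0.108 with an estimated correlation. Nfkbiz, which encodes the co-activator IkB-zeta, rose by 2.05 ± 0.12 on the log2 scale, from 31.9 ± 10.4 to 131 ± 31.0 CPM (edgeR adjusted p = 4.35e-06, NA 1.97, RB160 2.25). The neutrophil chemokine gene Cxcl1 rose by 2.65 ± 0.20, from 32.3 ± 8.08 to 203 ± 15.9 CPM (edgeR adjusted p = 6.17e-05, NA 2.41, RB160 3.23), and Zc3h12a, which encodes the ribonuclease Regnase-1, rose by 1.97 ± 0.20 (0.000737, NA 1.70, RB160 2.65). The matrix protease gene Adamts5 fell by 0.58 ± 0.06 and Col11a1, a collagen gene, by 0.48 ± 0.07 (edgeR adjusted p = 0.00152 and 0.011). In all, 35 genes rose and 23 fell, 12 of these 58 by at least 2-fold. All 58 had the same sign in both sets, which a fit over both sets favours, against 64.7% of all genes tested.

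Other cytokine and chemokine genes were called too. Il6 rose by 2.41 ± 0.38 (edgeR adjusted p = 0.019, NA 1.94, RB160 4.03), Cxcl5 by 4.21 ± 0.62 (0.0205, NA 2.87, RB160 4.62) and Ccl2 by 1.54 ± 0.30 (0.0466, NA 1.47, RB160 1.79). Nos2, the inducible nitric oxide synthase gene, rose by 5.01 ± 0.59 (edgeR adjusted p = 0.00742) to only 2.18 ± 1.32 CPM. Further genes with small p-values that rose were Nfkbia (0.55), Slc7a2 (1.02), Cyp7b1 (1.04), A4galt (0.92) and Ier3 (0.74), at edgeR adjusted p from 0.000703 to 0.011. Tmem119 (-0.56), Mecom (-0.41), Zfhx4 (-0.40), Sema3a (-0.55), Hey2 (-0.85) and Prx (-0.51) fell, at edgeR adjusted p from 0.00968 to 0.0238. The C/EBP transcription factor genes did not pass: Cebpd had a log2 fold change of 1.18 ± 0.24 (edgeR adjusted p = 0.0665, NA 1.03, RB160 1.70) and Cebpb of 0.54 ± 0.12 (0.102, NA 0.32, RB160 0.95). Lcn2, which encodes lipocalin-2, had 2.07 ± 0.64 (edgeR adjusted p = 0.233), with 1.45 in NA and 7.56 in RB160, and Steap4 had 2.07 ± 0.68 (0.262), with 0.07 in NA and 3.82 in RB160. Csf3, Ccl20 and Saa3 did not pass either (edgeR adjusted p = 0.358, 0.258 and 0.326).

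Of the 27 measured IL-17 target genes, 7 rose (Cxcl1, Cxcl5, Ccl2, Il6, Nfkbiz, Zc3h12a and Nos2), 0 fell and 20 did not pass. Adjusted over the list alone, 21 rose and 0 fell. The median log2 fold change was 1.31, 0.98 in NA and 1.85 in RB160, and limma's camera placed the list above the other genes at adjusted p = 9.71e-31, with adjusted p = 0.108 with an estimated correlation. The C/EBP target list, 9 of whose 20 genes are also in the IL-17 list, had 1 of 14 higher (Il6) and 0 lower, 9 and 1 adjusted over the list alone (camera adjusted p = 9.89e-07, and adjusted p = 0.212 with an estimated correlation). Of 6 C/EBP family genes 0 passed, 2 rose adjusted over the list alone (camera adjusted p = 0.000157, and adjusted p = 0.108 with an estimated correlation). Of 20 NF-kB feedback and subunit genes 3 rose (Nfkbiz, Nfkbia and Bcl3), 6 adjusted over the list alone (camera adjusted p = 1.22e-08, and adjusted p = 0.212 with an estimated correlation). Of 15 chemokine genes 3 rose (Cxcl1, Cxcl5 and Ccl2), 6 adjusted over the list alone (camera adjusted p = 7.47e-07, and adjusted p = 0.212 with an estimated correlation). Of 17 contractile and myofibroblast genes 0 passed, while 9 fell adjusted over the list alone, Cnn1 having -0.26 ± 0.07 and Myl9 -0.31 ± 0.08 (camera adjusted p = 7.29e-08 downward, and adjusted p = 0.256 with an estimated correlation). Camera also placed RNA-binding regulators of inflammatory mRNA, glycolysis, unfolded protein response and immediate early genes above, and extracellular matrix, cholesterol synthesis, cell cycle, epithelial and skeletal muscle genes below the other genes, at adjusted p from 0.000157 to 0.0321. For these 9 lists adjusted p lay between 0.238 and 0.831 with an estimated correlation, and the only called members were Zc3h12a, Ier3 and Col11a1. The cell cycle list (camera adjusted p = 0.0321) lost its call and turned direction without siControl_IL17 replicate 1 (0.633) or siControl replicate 2 (0.102), and lost its call without siControl_IL17 replicate 3 (0.0548), in a range of 3.17e-08 to 0.633. Of 14 fibroblast markers 0 passed, 3 rose and 5 fell adjusted over the list alone. Adjusted over the list alone, 3 reported IMP-bound mRNAs rose and 1 fell. The call count depended on single libraries and on the tool: it was 9 without siControl_IL17 replicate 3, 10 without siControl replicate 3 and 98 without siIMP2_IL17 replicate 3, 193 by DESeq2, and 1 without the title-set term. Leaving out 1 library ended the call of Ccl2 in 9 of 12 fits, Cxcl5 in 5, Bcl3 in 4, Il6 in 3 (siControl_IL17 replicate 1, siControl replicate 2 or siControl_IL17 replicate 3) and Nos2 in 1 (siControl_IL17 replicate 3), and ended in at least 1 fit the calls of A4galt, Col11a1, Cyp7b1, Hey2, Ier3, Mecom, Prx, Sema3a, Tmem119 and Zfhx4.

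The second comparison asked the same of cells with the IMP2 siRNA. IL-17 again raised Nfkbiz, by 2.30 ± 0.12 from 22.6 ± 3.84 to 109 ± 6.57 CPM (edgeR adjusted p = 1.42e-06, NA 2.19, RB160 2.47), and Cxcl1, by 3.15 ± 0.24 from 4.74 ± 0.52 to 42.0 ± 12.47 CPM (5.2e-05, NA 2.90, RB160 3.48). Zc3h12a rose by 2.02 ± 0.20 (edgeR adjusted p = 0.000499), Ccl2 by 2.04 ± 0.32 (0.0123, NA 1.94, RB160 2.20), and its family member Ccl7 by 1.98 ± 0.30 (0.012). The transcription factor gene Cebpd rose by 1.38 ± 0.26 (edgeR adjusted p = 0.0381, NA 1.28, RB160 1.49), and Ccl20 by 2.56 ± 0.48 (0.0377, NA 2.20, RB160 3.35). Adamts5 fell by 0.58 ± 0.07 (edgeR adjusted p = 0.00169). In all, 47 genes rose and 23 fell, 18 of these 70 by at least 2-fold, all with the same sign in both sets, against 58.7% of all genes tested.

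Nfkbia (0.58), A4galt (1.52), Slc7a2 (1.18), Syt17 (0.83) and Tgfbr3 (0.80), the betaglycan gene, also rose, at edgeR adjusted p from 0.000441 to 0.00464, as did Bcl3 (1.10, 0.01). Nos2 had 117 counts over the siIMP2_IL17 libraries and 0 in the siIMP2 libraries, at least 39.3-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.01). Olfml2b (-0.47), C1qtnf1 (-0.60), Col11a1 (-0.46), Tmem119 (-0.56), Prr5l (-0.58), Pde8b (-0.49) and Cdon (-0.47) fell, at edgeR adjusted p from 0.01 to 0.0125, and the adipocyte regulator gene Pparg fell by 1.02 ± 0.17 (0.0205). Il6 had 2.05 ± 0.47 (edgeR adjusted p = 0.091, NA 1.43, RB160 3.16), Lcn2 2.89 ± 0.82 (0.234, NA 2.01, RB160 6.71) and Cebpb 0.16 ± 0.12 (0.922), and these did not pass. Cxcl5 had 8 counts after IL-17 and 0 before, at least 2.69-fold higher against the same floor, and did not pass (edgeR adjusted p = 0.558), nor did Csf3, Saa3 or Steap4.

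Of the 27 IL-17 target genes 8 rose (Cxcl1, Ccl2, Ccl7, Ccl20, Nfkbiz, Zc3h12a, Cebpd and Nos2), 0 fell and 19 did not pass, with 18 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.06e-32, and adjusted p = 0.194 with an estimated correlation). The list median was 1.31, 0.52 in NA and 2.15 in RB160. Of 20 NF-kB genes 3 rose (Nfkbiz, Nfkbia and Bcl3), 6 adjusted over the list alone (camera adjusted p = 6.86e-10, and adjusted p = 0.273 with an estimated correlation). Of 15 chemokine genes 5 rose (Cxcl1, Ccl2, Ccl7, Ccl20 and Cxcl16, the last named after its value was seen), also 5 adjusted over the list alone (camera adjusted p = 2.07e-07, and adjusted p = 0.276 with an estimated correlation). Of 14 C/EBP target genes 0 rose and Pparg fell, 4 and 1 adjusted over the list alone (camera adjusted p = 5.36e-06 upward, and adjusted p = 0.276 with an estimated correlation). Of 34 extracellular matrix genes Col11a1 fell, and of 17 contractile genes 0 passed and 1 fell adjusted over the list alone, both lists lying below the other genes (camera adjusted p = 3.46e-06, and adjusted p = 0.276 with an estimated correlation). RNA-binding regulators lay above, and cholesterol synthesis, oxidative phosphorylation and adipocyte lists below, at camera adjusted p from 0.00667 to 0.0426 and at adjusted p from 0.276 to 0.797 with an estimated correlation. The count was 13 without siIMP2 replicate 3, 17 without siIMP2_IL17 replicate 3 and 117 without siControl replicate 3, 171 by DESeq2, and 2 without the title-set term. Leaving out 1 library ended the calls of Cebpd and of Ccl20 in 8 of 12 fits each, Pparg and Ier3 in 5, Ccl2 in 3 (siIMP2 replicate 1, siIMP2 replicate 2 or siIMP2_IL17 replicate 3) and Nos2 in 1 (siIMP2 replicate 3), and ended in at least 1 fit those of Bcl3, C1qtnf1, Ccl7, Cdon, Col11a1, Olfml2b, Pde8b, Prr5l and Tmem119.

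**Figure D3:**
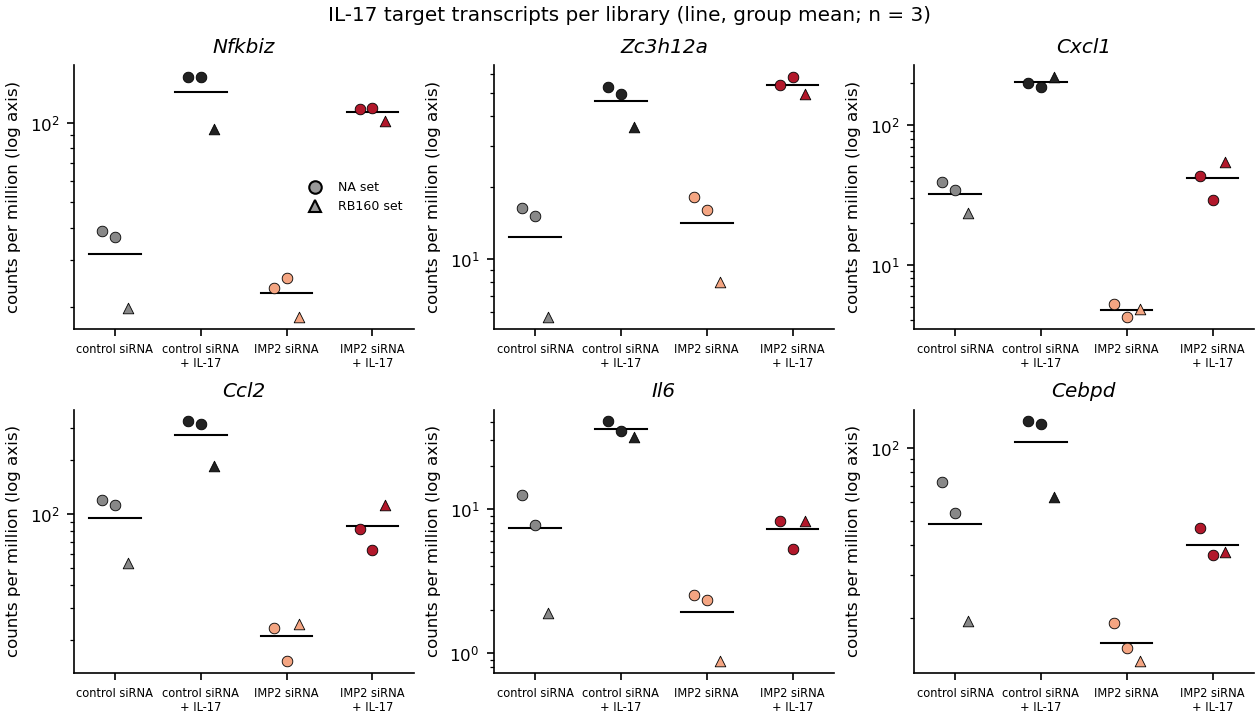
CPM per library on a log axis for IL-17 target genes in the 4 groups, with each point 1 library, marker for the title set and the group mean drawn. Cxcl1 averages 32.3, 203, 4.74 and 42.0 CPM, and Nfkbiz averages 31.9, 131, 22.6 and 109 CPM, in siControl, siControl_IL17, siIMP2 and siIMP2_IL17.

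The third comparison asked what the IMP2 siRNA changed in unstimulated cells. Of 17 listed contractile and myofibroblast genes 16 rose, and of 14 fibroblast markers 10 fell and 1 rose, with adjusted p = 0.218 with an estimated correlation for each list. Nppb, which encodes the natriuretic peptide BNP, rose by 3.77 ± 0.14 from 2.49 ± 0.73 to 35.4 ± 15.7 CPM (edgeR adjusted p = 2.46e-08, NA 3.92, RB160 3.33), and Cnn1, the smooth muscle calponin gene, by 1.38 ± 0.07 (1.54e-07, NA 1.39, RB160 1.37). Pdgfra, the platelet-derived growth factor receptor alpha gene, fell by 2.23 ± 0.11 (edgeR adjusted p = 1.54e-07) in both sets (NA -2.25, RB160 -2.16), and Dcn, the decorin gene, by 2.65 ± 0.24 (5.49e-06). Of 27 IL-17 target genes 11 fell and 4 rose before any stimulus, with adjusted p = 0.72 with an estimated correlation, and Cxcl1 fell by 2.77 ± 0.24 (edgeR adjusted p = 4.15e-06, NA -2.95, RB160 -2.28). In all, 2212 genes rose and 2293 fell, 32.9% of the genes tested, of which 265 rose and 387 fell by at least 2-fold. Of the 4505 called genes 4467 (99.2%) had the same sign in both sets, against 72.6% of all genes tested.

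Fhl1 (1.15), Actg2 (1.30), Siglecg (2.17), Dnajb5 (1.25), Tspan2 (1.20) and Gadd45b (1.02) rose, at edgeR adjusted p from 1.58e-07 to 4.6e-07. Car13 (-1.57), Sfrp1 (-2.20), which encodes a secreted WNT antagonist, Chmp3 (-1.12), Syt13 (-1.83), the gelatinase gene Mmp9 (-3.08) and Emilin2 (-1.06) fell, at edgeR adjusted p from 1.54e-07 to 3.27e-07. Among inflammatory genes Ccl2 fell by 2.13 ± 0.32 (edgeR adjusted p = 0.000278), with -2.62 in NA and -1.12 in RB160. Cebpd fell by 1.5 ± 0.26 (edgeR adjusted p = 0.00082), with -1.88 in NA and -0.55 in RB160, and Il6 fell by 1.89 ± 0.47 (0.00762), with -1.99 in NA and -1.08 in RB160. Lcn2 fell by 2.96 ± 0.79 (edgeR adjusted p = 0.0122), with -3.13 in NA and -0.66 in RB160, and Nfkbiz fell by 0.47 ± 0.12 (0.0108), with -0.62 in NA and -0.12 in RB160. Steap4 fell by 3.08 ± 1.10 (edgeR adjusted p = 0.0466) from 0.34 ± 0.09 CPM. In the other direction, Csf3, which encodes G-CSF, rose by 3.17 ± 0.36 from 0.24 ± 0.17 to 2.12 ± 1.21 CPM (edgeR adjusted p = 3.28e-05, NA 2.90, RB160 3.04). Cebpb (-0.19 ± 0.12), Zc3h12a (0.21 ± 0.20), Ccl20 and Saa3 did not pass (edgeR adjusted p = 0.264, 0.462, 0.938 and 0.35). Cxcl5 had 6 counts in siControl and 0 in siIMP2, at least 1.98-fold lower against the floor, and did not pass (0.117).

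Of 17 contractile and myofibroblast genes 16 rose and 0 fell, as they did adjusted over the list alone, with Itga5 at 1.32 ± 0.08 and Ankrd1 at 1.26 ± 0.08 (camera adjusted p = 2.54e-13, and adjusted p = 0.218 with an estimated correlation). Of 14 fibroblast markers 10 fell, Prrx1 by 0.89 ± 0.07 and Pdgfrb by 0.50 ± 0.06, and Col1a1 alone rose, with the same counts adjusted over the list alone (camera adjusted p = 2.58e-05, and adjusted p = 0.218 with an estimated correlation). Of 35 cell cycle genes 20 fell and 0 rose, 25 adjusted over the list alone, with Mcm2 at -0.46 ± 0.07 and Tyms at -0.65 ± 0.10 (camera adjusted p = 2.86e-07, and adjusted p = 0.62 with an estimated correlation). Of 20 p53 target genes 13 rose and Sesn1 fell, also adjusted over the list alone, with the apoptosis gene Pmaip1 at 1.30 ± 0.09 and the cell cycle inhibitor gene Cdkn1a at 0.54 ± 0.05 (camera adjusted p = 2.58e-05, and adjusted p = 0.218 with an estimated correlation). Glycolysis genes rose in 11 of 20 cases, Gapdh by 0.48 ± 0.05 and Aldoa by 0.54 ± 0.07, while Gpi1 fell, 12 and 3 adjusted over the list alone (camera adjusted p = 0.00347, and adjusted p = 0.62 with an estimated correlation).

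Of the 27 IL-17 target genes 11 fell, 4 rose and 12 did not pass, the same adjusted over the list alone. Those that rose were Csf3, Tnfaip3, the gene of the NF-kB inhibitor A20 (0.86 ± 0.10), and Ptgs2 and Il34, which were named after their values were seen. The list median was -1.25, -1.12 in NA and -0.12 in RB160 (camera adjusted p = 0.0296, and adjusted p = 0.72 with an estimated correlation). Of 14 C/EBP target genes 8 fell and 2 rose (Csf3 and Ptgs2), 9 and 3 adjusted over the list alone, with Lbp at -3.09 ± 0.37 and C3 at -1.77 ± 0.23 (camera adjusted p = 0.0245, and adjusted p = 0.62 with an estimated correlation). Of 20 NF-kB genes 13 fell, Bcl3 by 1.43 ± 0.16 and Nfkb2 by 0.58 ± 0.07, and 2 rose, Tnfaip3 and Rela, the same adjusted over the list alone (camera adjusted p = 0.000384, and adjusted p = 0.553 with an estimated correlation). Of 15 chemokine genes 7 fell and 0 rose, also adjusted over the list alone, with Ccl7 at -2.07 ± 0.30 and Ccl9 at -1.27 ± 0.19 (camera adjusted p = 0.0114, and adjusted p = 0.62 with an estimated correlation). Interferon-stimulated genes fell in 8 of 20 cases and rose in 0, also adjusted over the list alone, Gbp2 by 1.58 ± 0.18 (camera adjusted p = 0.00159, and adjusted p = 0.553 with an estimated correlation). Of 6 C/EBP family genes Ddit3 and Cebpg rose and Cebpd fell. Unfolded protein response genes rose in 8 of 23 cases, Trib3 by 1.37 ± 0.17, and Pdia3 and Calr fell, the same adjusted over the list alone (camera adjusted p = 0.0486, and adjusted p = 0.72 with an estimated correlation).

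The remaining lists had no camera call in unstimulated cells. IL-17 receptor signalling genes rose in 10 of 25 cases and fell in 2 (Il17rd and Btrc), 10 and 3 adjusted over the list alone. Of 17 RNA-binding regulators 6 fell, Zfp36l1 by 0.66 ± 0.08, and 0 rose (1 higher and 6 lower adjusted over the list alone). Of 21 m6A writers, erasers and readers 5 fell, the methyltransferase gene Mettl3 by 0.60 ± 0.07, and 2 rose (Alkbh5 and Ythdf1). Reported IMP-bound mRNAs went both ways, 4 of 20 higher and 5 lower, with Lims2 at 2.02 ± 0.19 and H19 at -2.14 ± 0.30. Extracellular matrix genes rose in 14 of 34 cases, Col4a1 by 0.73 ± 0.07, and fell in 8 (9 adjusted over the list alone). Of 14 matrix metalloproteinase genes 3 rose, Mmp17 by 2.06 ± 0.14, and 6 fell (8 adjusted over the list alone). Immediate early genes rose in 12 of 24 cases, Dusp1 by 0.68 ± 0.08, and Fos, Junb, Egr1 and Egr3 fell (14 and 6 adjusted over the list alone). Cholesterol synthesis genes rose in 4 of 24 cases and fell in 3, and nuclear oxidative phosphorylation genes in 4 and 3 of 40 (3 and 1 adjusted over the list alone). Of 40 translation and ribosomal protein genes 2 fell (Rpl7 and Eef2, 0 adjusted over the list alone). Markers of other cells moved both ways: Acta1, Tnni1 and Tnnt2 of 6 skeletal muscle markers and Krt19 and Krt8 of 4 epithelial markers rose, and Cdh1 fell. Spp1 and Col2a1 of 8 chondrocyte and osteoblast markers, Pparg and Fabp4 of 5 adipocyte markers, Stmn2 and Map2 of 5 neural markers, Mrc1 of 5 macrophage markers and Cdh5 of 6 endothelial markers fell. Of 4 sex-linked genes and 13 mitochondrially encoded genes 0 passed, and 0 of 10 erythroid markers had enough counts to be tested. Adjusted over the list alone, 2 macrophage, 3 neural and 0 of the sex-linked markers fell, and 3 epithelial markers rose. Without the title-set term the count of called genes was 321, and leaving out 1 library ended the call of Steap4 in 8 of 12 fits, Eef2, Rpl7 and Tnnt2 in 4, Cdh1 and Cdh5 in 3, and Fabp4 in 1 (siIMP2 replicate 3).

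**Figure D4:**
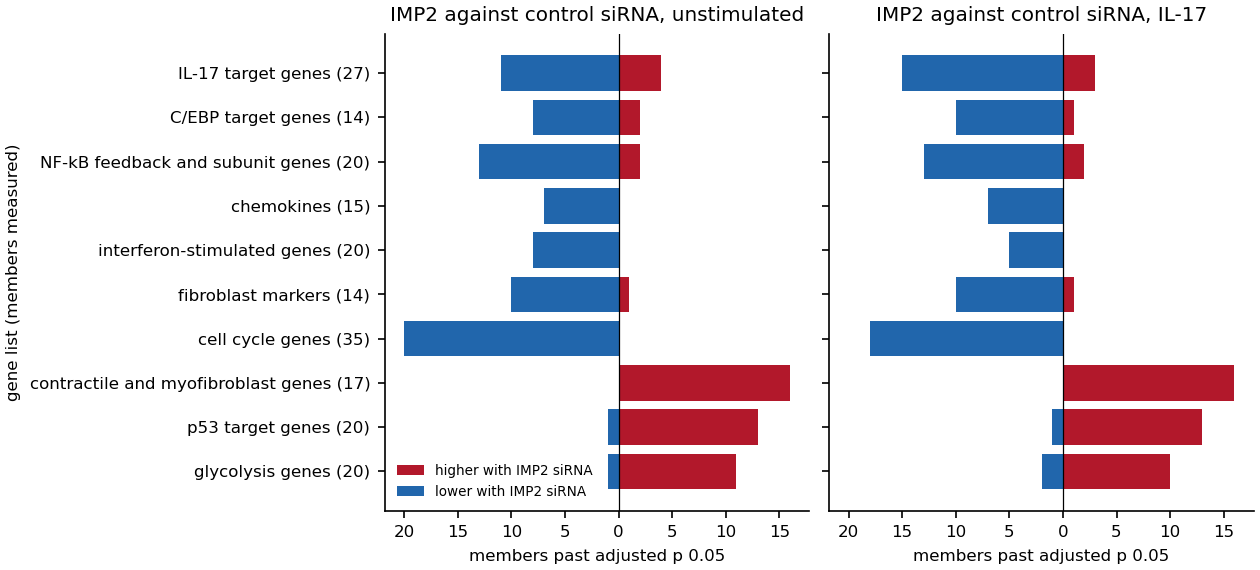
Number of members of 10 gene lists past an edgeR adjusted p of 0.05 with the IMP2 siRNA against the control siRNA, in unstimulated cells on the left and after IL-17 on the right, with bars to the right for members higher, bars to the left for members lower and the members measured in brackets. Contractile genes show 16 higher and 0 lower in both panels, and IL-17 target genes show 11 lower unstimulated and 15 lower after IL-17.

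The fourth comparison asked the same after IL-17. Of 17 contractile genes 16 rose, and of 27 IL-17 target genes 15 fell and 3 rose, with adjusted p = 0.202 and 0.737 with an estimated correlation. Nppb rose by 3.24 ± 0.14 (edgeR adjusted p = 7.96e-08, NA 3.18, RB160 3.27) and Cnn1 by 1.49 ± 0.07 (9.01e-08), and Pdgfra fell by 2.31 ± 0.11 (9.01e-08, NA -2.42, RB160 -2.22). Cxcl1 fell by 2.27 ± 0.20 (edgeR adjusted p = 4.94e-06) in both sets (NA -2.46, RB160 -2.03), and Il6 fell by 2.25 ± 0.37 (0.000569, NA -2.49, RB160 -1.95). Cebpb fell by 0.57 ± 0.12 (edgeR adjusted p = 0.00305, NA -0.45, RB160 -0.79) and Cebpd by 1.31 ± 0.25 (0.00136, NA -1.63, RB160 -0.76). In all, 2289 genes rose and 2292 fell, 33.4% of those tested, 276 and 406 by at least 2-fold, and 4550 of the 4581 (99.3%) had the same sign in both sets, against 72.7% of all genes tested.

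Fhl1 (1.23), Actg2 (1.28), Siglecg (2.12), Pkp2 (0.84) and Tspan2 (1.17) rose, at edgeR adjusted p from 9.01e-08 to 4.32e-07. Car13 (-1.68), Sfrp1 (-2.20), Chmp3 (-1.11), Ptpn13 (-1.34), Nrg1 (-1.05) and Gas1 (-2.11) fell, at edgeR adjusted p from 9.01e-08 to 2.87e-07. Ccl2 fell by 1.63 ± 0.30 (edgeR adjusted p = 0.00122), with -2.15 in NA and -0.72 in RB160. Cxcl5 fell by 3.81 ± 0.59 (edgeR adjusted p = 0.000659) from 1.05 ± 0.17 CPM, and Steap4 by 2.85 ± 0.66 (0.0053) from 2.34 ± 3.50 CPM. Lcn2 fell by 2.14 ± 0.65 (edgeR adjusted p = 0.0219), with -2.58 in NA and -1.51 in RB160. Csf3 rose by 2.47 ± 0.31 (edgeR adjusted p = 7.03e-05). Nfkbiz (-0.22 ± 0.11), Zc3h12a (0.26 ± 0.18), Ccl20 (0.95 ± 0.41) and Saa3 (-1.09 ± 0.66) did not pass (edgeR adjusted p = 0.154, 0.288, 0.0959 and 0.223).

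Of the 27 IL-17 target genes 15 fell, 3 rose (Csf3, Tnfaip3 and Il34) and 9 did not pass, the same adjusted over the list alone, with a median of -1.10, -1.29 in NA and -0.72 in RB160 (camera adjusted p = 0.0118, and adjusted p = 0.737 with an estimated correlation). C/EBP target genes fell in 10 of 14 cases, Pparg by 2.22 ± 0.16, and Csf3 rose, also adjusted over the list alone (camera adjusted p = 0.0108, and adjusted p = 0.597 with an estimated correlation). Of 6 C/EBP family genes Cebpa, Cebpb and Cebpd fell and Ddit3 and Cebpg rose. NF-kB genes fell in 13 of 20 cases and rose in 2 (Tnfaip3 and Rela), and chemokine genes fell in 7 of 15 and rose in 0, the same counts adjusted over the list alone. Their camera adjusted p were 0.000162 and 0.0118, and adjusted p = 0.43 and 0.598 with an estimated correlation. Of 17 contractile genes 16 rose, also adjusted over the list alone (camera adjusted p = 1.07e-13, and adjusted p = 0.202 with an estimated correlation), and of 14 fibroblast markers 10 fell and Col1a1 rose (1.69e-05, and adjusted p = 0.202 with an estimated correlation). Cell cycle genes fell in 18 of 35 cases and rose in 0, 22 adjusted over the list alone (camera adjusted p = 9.96e-07, and adjusted p = 0.658 with an estimated correlation). Of 20 p53 target genes 13 rose and Sesn1 fell, 14 and 2 adjusted over the list alone (camera adjusted p = 1.17e-05, and adjusted p = 0.202 with an estimated correlation). Interferon-stimulated genes fell in 5 of 20 cases, Gbp2, Stat2, Bst2 and Oasl2 among them, also adjusted over the list alone (camera adjusted p = 0.00686, and adjusted p = 0.43 with an estimated correlation). Glycolysis genes rose in 10 of 20 cases and Gpi1 and Pdk1 fell, 11 and 2 adjusted over the list alone (camera adjusted p = 0.0256, and adjusted p = 0.658 with an estimated correlation). Among markers of other cells, Acta1, Tnni1 and Tnnt2 of 6 skeletal muscle markers rose (camera adjusted p = 0.0198, and adjusted p = 0.43 with an estimated correlation) and Pparg, Fabp4 and Cebpa of 5 adipocyte markers fell (0.0378, and adjusted p = 0.43 with an estimated correlation). Mrc1 and Cd14 of 5 macrophage markers, Stmn2 of 5 neural markers, Spp1 and Col2a1 of 8 chondrocyte and osteoblast markers and Cdh1 of 4 epithelial markers fell, Krt8, Krt18 and Krt19 rose, and 0 of 6 endothelial markers passed. The other lists had no camera call: 9 of 25 IL-17 receptor signalling genes rose and 2 fell, 6 of 17 RNA-binding regulators fell, 2 of 21 m6A genes rose and 7 fell, and 4 of 20 IMP-bound mRNAs rose and 6 fell. Extracellular matrix genes rose in 14 of 34 cases and fell in 9, matrix metalloproteinase genes in 3 and 4 of 14, immediate early genes in 9 and 4 of 24, and unfolded protein response genes in 5 and 2 of 23. Without the title-set term the count of called genes was 327, and leaving out 1 library ended the call of Cebpa in 10 of 12 fits, Mrc1 in 6, Lcn2 and Cd14 in 4, Stat2 in 2 (siControl_IL17 replicate 3 or siIMP2_IL17 replicate 3), Steap4 in 1 (siControl_IL17 replicate 3) and Krt18 in 1 (siIMP2_IL17 replicate 1).

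The fifth comparison asked whether the fold response to IL-17 differed between the siRNAs. Cxcl1 rose with both siRNAs, and the difference of its log2 fold changes, siIMP2 less siControl, was 0.50 ± 0.31, with 0.49 in NA and 0.25 in RB160. The difference was 0.25 ± 0.17 for Nfkbiz, -0.38 ± 0.17 for Cebpb, 0.20 ± 0.35 for Cebpd, -0.35 ± 0.61 for Il6 and 0.50 ± 0.42 for Ccl2, and none of the 16 panel genes passed (edgeR adjusted p = 1 for each). On the linear scale the gain in mean CPM was smaller with the IMP2 siRNA for 20 of the 27 IL-17 target genes and larger for 7. The mean of Cxcl1 grew by 171 CPM with siControl and by 37.2 CPM with siIMP2, 21.8% of the siControl gain, with 18.9% for Il6, 36.1% for Ccl2, 42.3% for Cebpd and 23.1% for Lcn2. The gain was 87.8% for Nfkbiz, 105% for Ptges, 118% for Zc3h12a, 225% for Tnfaip3, 232% for Ccl20 and 238% for Csf3. The gains of Ccl20 were only 0.637 CPM with siControl and 1.475 CPM with siIMP2, and those of Csf3 0.229 and 0.544 CPM. Lcn2, Ptges, Tnfaip3 and Csf3 passed for IL-17 with neither siRNA, and the ratios of the gains were not tested. These gains pool both title sets, between which the siRNA effects on Ccl2 and Cebpd and the IL-17 effects on Il6 and Lcn2 differed.

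No gene passed for the difference of the fold responses by edgeR (0 of 13702), DESeq2 (0) or limma-voom (0), and 152 genes had an unadjusted p below 0.05. Of the 373 genes called for the average IL-17 effect, the difference opposed that effect in 179 (48.0%), with a signed median of 0.01. Over the genes called under each setting this share was 26.2% without siControl replicate 3, 72.2% without siControl replicate 1 and 19.4% at an average log2 fold change of at least 1. For the 373 genes limma's fry, a test of a common direction by rotation in a model across all genes, gave an unadjusted p = 0.926. Across these 373 genes, which are not independent replicates, the IL-17 log2 fold changes with siIMP2 followed those with siControl at r = 0.95 and a slope of 1.17. These genes were chosen by their average over both siRNAs, which favours a high r, and across all genes tested r was 0.435. Large fold changes weigh most in the slope. The fold change of Nos2 with siIMP2 rests on 0 counts before IL-17, so it is only a fitted value. Over the genes called under each setting the slope was 0.719 from the NA libraries alone, 0.743 without siControl replicate 2 and 0.734 with no filter, so its side of 1 depended on the setting. Both IL-17 comparisons called 36 genes, all in the same direction, 25 higher and 11 lower, where independent lists would share 0.12 and 0.0386. The siRNA comparisons, which share no library, both called 3658 genes, 1813 higher and 1845 lower, where independent lists would share 370 and 384, with r = 0.834 across all genes tested. No member of any list passed, also adjusted over the list alone. Camera placed unfolded protein response genes (adjusted p = 0.000723, and adjusted p = 0.838 with an estimated correlation) and adipocyte markers (0.0207, and adjusted p = 0.558 with an estimated correlation) below the other genes. The IL-17 target list had camera adjusted p = 0.742 with a median of 0.13 and a mean of 0.20, although the test's direction was downward. Without siControl replicate 3 the list was called upward (camera adjusted p = 0.000218), and downward without siControl replicate 1 (0.0463) or siIMP2_IL17 replicate 3 (0.000903), in a range of 0.000218 to 0.978 on leaving out 1 library.

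Averaged over both siRNAs, IL-17 raised 179 genes and lowered 194, all 373 with the same sign in both sets, against 65.1% of all genes tested. Of the 27 IL-17 target genes 14 rose and 0 fell (23 and 0 adjusted over the list alone). The count of 373 was 199 from the NA libraries alone (131 higher and 68 lower), 4 with no title-set term, 654 by DESeq2 and 674 with no filter. It was 198 without siIMP2 replicate 3, 233 without siIMP2 replicate 2 or siIMP2_IL17 replicate 3, and 244 without siControl replicate 3. Averaged over both stimulations, the IMP2 siRNA raised 3307 genes and lowered 3470, and 6579 of the 6777 (97.1%) had the same sign in both sets, against 74.5% of all genes tested. Of the IL-17 target genes 17 fell and 4 rose in that average (18 and 4 adjusted over the list alone), while 16 of 17 contractile genes rose, 30 of 35 cell cycle genes fell and 13 of 20 interferon-stimulated genes fell. The authors' deposited table, which covers 20274 genes, gave 8 genes higher and 0 lower for IL-17 with the control siRNA and 6 and 0 with the IMP2 siRNA at an adjusted p below 0.05. The authors' deposited table gave 72 higher and 92 lower for the IMP2 siRNA in unstimulated cells and 67 and 103 after IL-17. Of these calls in the authors' deposited table, 7, 6, 164 and 169 were also called by edgeR here.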

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

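The tests of the share of fibroblasts, the stability of spliced mRNA, the size of the response, macrophages, cells or library preparation between the sets and the leading 7-mer were chosen only after the results were seen, as were the offsets for GC content and length. All p-values here are edgeR quasi-likelihood values with Benjamini-Hochberg adjustment.

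Between the siRNAs 6777 genes differed on average over both stimulations. After offsets for GC content and transcript length 6056 of them (89.36%) were still called, which argues against those trends as the whole cause. Of 39 markers of other cell types 11 were lower and 7 higher. Of all 13702 genes tested 3470 were lower and 3307 higher, so some lower markers were likely whatever the share of fibroblasts. These counts therefore cannot weigh a lower share of fibroblasts. Direct silencing of most lower genes through a match of the siRNA seed in the 3' UTR is argued against. Of the 12316 genes whose 3' UTR was searched, 33.9% of the 3283 called lower held any of the 4 leading 7-mers of Igf2bp2 transcripts. The share was 27.21% of the 5979 uncalled genes, standardised to the same UTR lengths, an excess of 6.69 percentage points. Genes that move downstream of a silenced gene need hold no match. Off-target silencing as the whole cause therefore cannot be weighed by this search. For part of the genes direct silencing stays open. The 7-mer most associated with lower values (z = -9.308) occurs in Igf2bp2 transcripts, as do 5318 of the 15643 7-mers tested. Its z for the siRNA effect was -8.51 unstimulated and -9.495 after IL-17, against 0.6 for the average IL-17 effect. The largest positive z of any 7-mer was 3.606. With the log2 changes permuted over the genes, the most negative z was -3.518. This leading 7-mer was held by 549 (16.72%) of these 3283 genes against 8.81% of the 5979, not standardised for length and chosen for that association. Of the 15 searched IL-17 target genes called lower 4 held it, against 1320 of all 12316 genes. Some genes may thus be lower through the seed, although the siRNA sequence is not given in the sources used here. Of 100 regroupings of the 12 libraries only 1, the real one, called as many genes and the highest other called 1. This argues against a chance split of these libraries, though the other regroupings leave the siRNA effect in the spread, which favours few calls. Regroupings cannot weigh a chance difference between cultures. A lower level of IMP2 itself remains untested against a second siRNA.

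Of the 27 IL-17 target genes 17 were lower with the IMP2 siRNA on average and 11 in the test of unstimulated cells, with medians over all 27 of -1.25 unstimulated and -1.10 after IL-17 (NA -1.12 and -1.29, RB160 -0.12 and -0.72). A smaller response to IL-17 as the whole cause is argued against by these 11 and by the median of the 17 in unstimulated cells. That median was -1.892 (95% interval -2.77 to -1.37), or -1.504 with 2 genes at 0 counts set at their bound, beside -1.63 after IL-17. However, choosing the 17 by an average that includes unstimulated cells favours a low value. The RB160 medians of the siRNA effect, from 1 library per group, also go with that explanation. Medians of the IL-17 response over all 27 with siControl and siIMP2 were 1.85 and 2.15 in RB160, and 0.98 and 0.52 in NA. However, the median over the 27 of each gene's own difference, siIMP2 less siControl, was 0.0211 in NA and -0.184 in RB160. The direction within a set thus differed between these measures. The 95% intervals of this paragraph resample genes, whose estimated correlation was 0.441, and leave out the spread between libraries. Lower stability of the spliced mRNA alone stays open for the list: reads outside exons could be measured for 8 of the 17 and had a median of -1.797 beside -1.83 in exons, with a wide 95% interval of -2.20 to -0.25. Of these 8, Cxcl1, Il1rn, Ccl2, Il6 and Ccl7 were called lower outside exons too, and a second interval, for the median outside exons less 0.5 times the exon median, was -1.02 to -0.03, which goes against this explanation but was chosen after the first had been seen. Of the 17 listed macrophage markers only 5 had enough counts to be tested, at 0.357 to 8.37 CPM on average over the control siRNA libraries. Their median was -0.3136 with an SD of 0.978, and values from -2.21 to 0.37, so fewer macrophages in the cultures stay open too.

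Between the title sets 9521 genes differed, Stmn2 with 61.7 CPM in NA and 0.724 CPM in RB160 and Pdgfra with 11.6 and 78.2 CPM. After offsets for GC content and transcript length 78.85% of them were still called in the same direction, which argues against those trends as the whole cause. Other splits of the libraries into 8 and 4 called at most 225 genes, and 1 of 100 splits, the real one, called as many. This argues against a chance split of these libraries, though the other splits leave the difference between the sets in the spread. Whether the cells or the library preparation differed cannot be told apart, because the labels tie neither to the sets, and no biological explanation was tested.

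The siRNA effect, averaged over both stimulations, differed between the sets for 902 genes by a test of the difference itself, and the IL-17 effect for 42, with 5 residual degrees of freedom. Because RB160 holds 1 library per group, these tests measure mostly the spread between the NA libraries. For the siRNA effect the RB160 value less the NA value was 0.552 for Igf2bp2 (adjusted p = 0.0312), 0.3049 for Igf2bp3 (0.0439), 1.075 for Cebpd (0.00569), 0.4962 for Nfkbiz (0.00214) and 1.441 for Ccl2 (0.000619), so the decrease was smaller in RB160 for each of these. Of all 902 genes, 433 had siRNA effects of opposite sign in the sets, 267 the same sign and a smaller effect in RB160, and 202 a larger one, with no test of the sign within a set. Has2 (-0.99 in NA and 0.65 in RB160), Csrp2 (0.79 and -0.58) and Lif (-0.85 and 0.42), chosen after their values were seen, are among the 433. For the IL-17 effect the RB160 value less the NA value was 6.221 for Lcn2 (adjusted p = 0.000111), 0.9445 for Zc3h12a (0.00254), 2.014 for Il6 (0.0235), 8.314 for Saa3 (0.00125), which lies near the floor, and 3.785 for Steap4 (0.0222).

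Reads assigned to a gene beyond its exon counts, which are outside the main measurement, differed between the siRNAs for 2152 of 11536 genes, 1460 higher and 692 lower. They were lower for Cxcl1 (-2.39), Il1rn (-2.20), Ccl2 (-1.94), Il6 (-1.80) and Ccl7 (-1.79). Igf2bp2 had -0.23 outside exons (adjusted p = 0.278) and -2.74 in exons.

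The 3 against 3 comparisons make 10 splits, too few for a share under 0.05. The real split called 58 genes and the highest other 26 for IL-17 with the control siRNA, 70 and 0 with the IMP2 siRNA, 4505 and 1 for the IMP2 siRNA in unstimulated cells, and 4581 and 0 after IL-17. For the difference of the responses the real grouping called 0 genes, so all 100 of 100 regroupings called as many, up to 6734. The regrouping with 6734 has all 6 libraries of 1 siRNA on a side, so its contrast is that between the siRNAs. For the average IL-17 effect 4 of 100 regroupings called at least 373 genes, the highest 6580, and such counts point to a structure of the samples. Of the 3 others the regrouping with 6580 has all 6 libraries of 1 siRNA on a side, so its contrast is that between the siRNAs. The other 2 have 5 on a side, but 10 of the 12 regroupings with 5 called at most 113, and the cause was not tested. With libraries moved only within a siRNA and title set, 1 of 72 regroupings, the real one, called as many and the highest other called 6. This argues against a chance split there.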

How the results depend on the processing

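Uniquely mapped reads and the offsets for GC content and length were chosen only after the results were seen, and neither moved a count of called genes by over 1.5 times. The offsets turned the balance of the siRNA calls, to 3949 higher and 3159 lower on average, 2764 and 2154 unstimulated and 2783 and 2026 after IL-17, and left 32 higher and 15 lower for IL-17 with the control siRNA. They also hold each library's mean deviation of log2 CPM, so they rescale whole libraries too. Whether the trends or this rescaling turned the balance was not tested. Of 676 results of named genes 0 reversed under any alternative that gave them a value (533 with only the groups compared, 610 at 1 CPM in 3 libraries, 669 in the NA libraries and 674 by uniquely mapped reads), and RLE and upper-quartile factors changed none of their calls. With no title-set term 224 lost their call, and by DESeq2 6 lost and 22 gained one. Over the fits that left out 1 library, 7891 of 8112 values kept their side of the threshold, 185 lost and 36 gained a call. No paired analysis was run, because the labels give no replicate numbers shared between groups. A block taken from the order of the titles could have been fitted but was not. A fold threshold lowers counts by construction. For the other moved values, among them counts that rose when fewer libraries entered, the cause was not tested. Cxcl5 and Nos2 had 0 counts in the siIMP2 libraries, so at this depth their folds against that group are lower bounds.

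For IL-17 with the control siRNA (58 genes), DESeq2 called 193, no filter beyond 1 count 221, no title-set term 1, only the groups compared 100, and a log2 fold change of at least 1 left 12. Leaving out 1 library gave 9 to 98: 18, 18 and 9 without siControl_IL17 replicates 1, 2 and 3, 23 and 10 without siControl replicates 2 and 3, 34 and 30 without siIMP2 replicates 1 and 2, and 32, 37 and 98 without siIMP2_IL17 replicates 1, 2 and 3. With the IMP2 siRNA (70 genes) these were 171, 179, 2, 349 and 18, with 46 from the NA libraries alone. Leaving out 1 library gave 13 to 117: 25, 18 and 13 without siIMP2 replicates 1, 2 and 3, 27 and 17 without siIMP2_IL17 replicates 1 and 3, and 117 without siControl replicate 3. The average IL-17 effect (373 genes) had 654 by DESeq2, 674 with no filter, 4 with no title-set term, 199 from the NA libraries alone and 36 at a log2 fold change of at least 1, and 198 (without siIMP2 replicate 3) to 490 (without siControl replicate 1) on leaving out 1 library. With no title-set term the IMP2 siRNA called 321 genes unstimulated, 327 after IL-17 and 1666 on average, and at a log2 fold change of at least 1 it called 652, 682 and 730. Leaving out 1 library kept these counts at 3222 to 4690, 3357 to 4804 and 6116 to 6584, and the difference of the responses at 0.

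With an estimated correlation 0 lists were called in each of the 7 comparisons. By fry, which does not compare a list with other genes, 3 lists were called for IL-17 with the control siRNA, 2 with the IMP2 siRNA, 8 for the average IL-17 effect, 21 for the average siRNA effect and 0 for the difference of the responses. For that difference, where 2 lists were called, 1 was called with no title-set term, 1 from the NA libraries alone, and 1 to 9 on leaving out 1 library.

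Over the genes called for the average IL-17 effect under each setting, r between the IL-17 responses was 0.7713 with no filter (674 genes), 0.7332 from the NA libraries alone (199 genes) and 0.7864 to 0.9628 on leaving out 1 library (198 to 490 genes), and the slope was 0.7336, 0.7185 and 0.7429 to 1.278. For the siRNA effects r was 0.2646 with no filter, 0.8999 with at least 1 CPM in 3 libraries, 0.7403 from the NA libraries alone, 0.9118 at an average log2 fold change of at least 1, and 0.7256 to 0.7977 on leaving out 1 library.

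List tests turned direction on leaving out 1 library. The cell cycle list for IL-17 with the control siRNA had camera adjusted p = 0.6331 without siControl_IL17 replicate 1 and 0.1025 without siControl replicate 2 (range 3.166e-08 to 0.6331). For the difference of the responses it had 0.03301 without siControl_IL17 replicate 1 and 6.434e-05 without siControl replicate 2 (range 4.417e-05 to 0.9427), and the IL-17 target list had 0.0002184 without siControl replicate 3 (range 0.0002184 to 0.9781).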

Other observations

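Averaged over both stimulations, markers of several cell lineages were among the genes that moved with the IMP2 siRNA, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 39 markers of cells other than fibroblasts 7 rose and 11 fell, beside 3307 and 3470 of all 13702 genes tested. Such markers therefore did not stand out from genes at large, and those below are examples. Acta1, the skeletal muscle actin gene, rose by 2.08 on the log2 scale from 33.8 to 150 CPM (adjusted p = 3.7e-07), and Krt19, a keratin gene, by 0.68 from 84.5 to 138 CPM (3.92e-06). Spp1, the osteopontin gene, fell by 0.98 from 2200 to 1083 CPM (adjusted p = 1.04e-05), Col2a1, a cartilage collagen gene, fell by 0.62 (2.1e-05), and Pparg fell by 1.93 from 6.30 to 1.72 CPM (4.32e-08). Among fibroblast markers Vim, at 2958 and 2951 CPM, did not pass (adjusted p = 0.983), while Lum fell by 2.59 (1.2e-05) and Col1a1 rose by 0.32 (0.000156). Vim and Lum were chosen after their values were seen.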
